A study of Mus musculus with 2 samples.

How the data were processed

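Total RNA of each sorted population was amplified to cDNA from 20 ng, and 5 µg of cDNA was labelled with biotin, per the labels' protocols. Each population was read on 1 array, with 5 mice stated for each sample. The labels do not say whether RNA or cells of these mice were pooled before the array. RMA and MAS5 (version 5.0) are named, without their roles, per the submitters' processing notes. Which of them made the values, and from which annotation build, is not given in the sources used here.

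The authors deposited 2 tables with the same values, the series value table and a table with gene names, and these were identical in all 45101 probe sets. The deposited expression values are on a log2 scale, from 1.42 to 14.55. The authors' deposited table adds a linear fold (the ratio of the c-Kit+ array over the c-Kit- array), which equals 2 raised to the difference of the log2 columns in every row, to within 5.5e-08 log2 units. This settles the log base and the direction. When sorted, the columns differ by at most 0.28, so the arrays had been brought to nearly the same distribution before deposit, and a change of total RNA per cell would not be seen. In 1411 probe sets the values are identical on both arrays. No detection calls, background values or raw intensities were used here. How far background alters the fold of a gene that is weak on 1 array was not tested, and such a fold may be too small or too large. The number of arrays limits the precision.

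Gene names come from the authors' deposited table. Of 45037 probe sets that are not controls, 37579 name 1 symbol, 1467 name several and 5991 name none. Symbols were updated through the gene identifier to the gene table of assembly GRCm38.p6, which held 34316 of the 37579 (91.3%), and 4282 symbols changed. The file's symbol was kept otherwise. Each gene took the probe set with the highest mean of both arrays, and probe sets of several symbols or none stayed out of gene comparisons. A gene counted as expressed if its value on the brighter array reached that array's median over the probe sets that are not controls. The arrays were compared as deposited, with no further scaling.

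The difference is the log2 value on the c-Kit+ array minus that on the c-Kit- array. With 1 array per group no test of the populations exists, so genes are counted by size, at 1, 2 and 3 log2 units. For 35 gene lists, the median difference of the expressed members was set against 10000 random lists of the same size, drawn from the expressed genes and matched on mean expression in 20 bins. The central 95% of the random medians describes these arrays and tests nothing about other mice. The procedure was tested on simulated data made from the centred differences of all 13516 expressed genes in random order. Of 200 unshifted lists of 20 genes, 6 fell outside the range, and both lists at each simulated shift of 0.5, 1 and 2 log2 units upward and of 1 and 2 downward were found. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

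Before the data were examined, the groups, the gene lists, the processing alternatives and the rule for naming genes were fixed. The rule names Kit and Ly6a, the 12 expressed genes with the largest difference on each side, unless another expressed probe set of the gene had the opposite sign, and up to 4 members of each list with the largest absolute difference. Further list members are named only to show what a count holds. The text does not name every gene that the rule takes, mostly in lists inside their random range, and 1 gene is not reported here. Lists cover the cell types that the gates could contain, functional groups, housekeeping genes and early-response genes. A further 3 lists, of goblet cell and pancreatic genes, were added after values had been seen and are used only in the closing observations. The alternatives were median scaling, quantile normalization, a pseudocount of 16 on the linear scale, no expression filter, a filter at the 75th percentile, the mean of all probe sets, leaving out cross-hybridizing probe set types (_x_at and _s_at), and the probe set with the smallest difference. For lists, members shared between cell type lists were left out, and random lists were drawn without matching. A second deposited summary of the same arrays would have been a further alternative, and both tables hold the same one.

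As signs of RNA quality, the 3' minus 5' probe set difference of Gapdh was 2.72 on the c-Kit+ array and 2.95 on the c-Kit- array, and that of Actb was 0.20 and -0.03. The 18 probe sets of the spiked bacterial and phage controls were higher on the c-Kit+ array by a median of 0.21 (0.01 to 0.39).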

Results

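Gene expression was measured in a pair of cell populations sorted from the lamina propria of the mouse small intestine, the connective tissue layer beneath the gut epithelium. Both populations lacked the lineage markers stained by an antibody cocktail and lacked Sca-1, and they differed in surface c-Kit, the receptor for stem cell factor. The submitters took the c-Kit+ population as innate lymphoid cells, a mixture of NKp46+ cells that make interleukin 22 and of cells resembling lymphoid tissue inducer (LTi) cells. They took the c-Kit- population as cells that are not innate lymphoid cells, and the question was how the profiles of these populations differ. The cells came from female BALB/c mice aged 8 weeks, with 5 mice stated for each sample. Each population was represented by 1 array, so no difference below has a replicate check, a standard error or a p-value, and every statement describes these 2 arrays only. After labelling from 20 ng of RNA, 45101 probe sets were read on each array, and their log2 values correlated with r = 0.95 across probe sets, which are not independent replicates. The median log2 value was 5.38 on the c-Kit+ array and 5.31 on the c-Kit- array. Of 20660 genes with a probe set of a single symbol, 13516 passed the expression filter on at least 1 array.

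The sort itself was visible in the RNA. Kit was 1.67 log2 units higher on the c-Kit+ array (9.10 against 7.43, or 3.18-fold) by its brighter probe set and 1.94 higher by its other probe set. Ly6a, which encodes Sca-1, read 6.20 on the c-Kit+ array and 5.62 on the c-Kit- array, a difference of 0.58, although both gates excluded Sca-1. Kit was used to sort the cells and is a check of the labels, not a finding. Genes often used as references were nearly level. Actb read 12.65 and 12.68, B2m read 12.75 and 12.71, and none of the 12 expressed housekeeping genes differed by 1 log2 unit.

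Expressed genes that differed by 2 log2 units (4-fold) or more numbered 120 on the side of the c-Kit+ array and 89 on the side of the c-Kit- array. At 1 log2 unit the counts were 772 and 914, which are 5.71% and 6.76% of the expressed genes, and at 3 log2 units they were 36 and 22. The larger side at 1 log2 unit depended on scaling, with 842 and 758 after quantile normalization and 665 and 1103 after median scaling. With a pseudocount of 16 the counts at 2 log2 units were 63 and 48, and with the least different probe set of each gene 78 and 51. The median difference over all expressed genes was -0.07. As a measure of technical scatter within the arrays, the differences given by separate probe sets of the same gene disagreed by a median of 0.43 log2 units and by 1.24 at the 90th percentile. This scatter leaves out the spread between mice, sorts and labelling reactions. Of 50 genes that differed by 2 or more and had several expressed probe sets, 36 (72%) had every probe set on the same side. Among all 5012 genes with several expressed probe sets that share was 53.7%. Every probe set was past 1 log2 unit in 23 of the 50 genes.

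**Figure D1:**
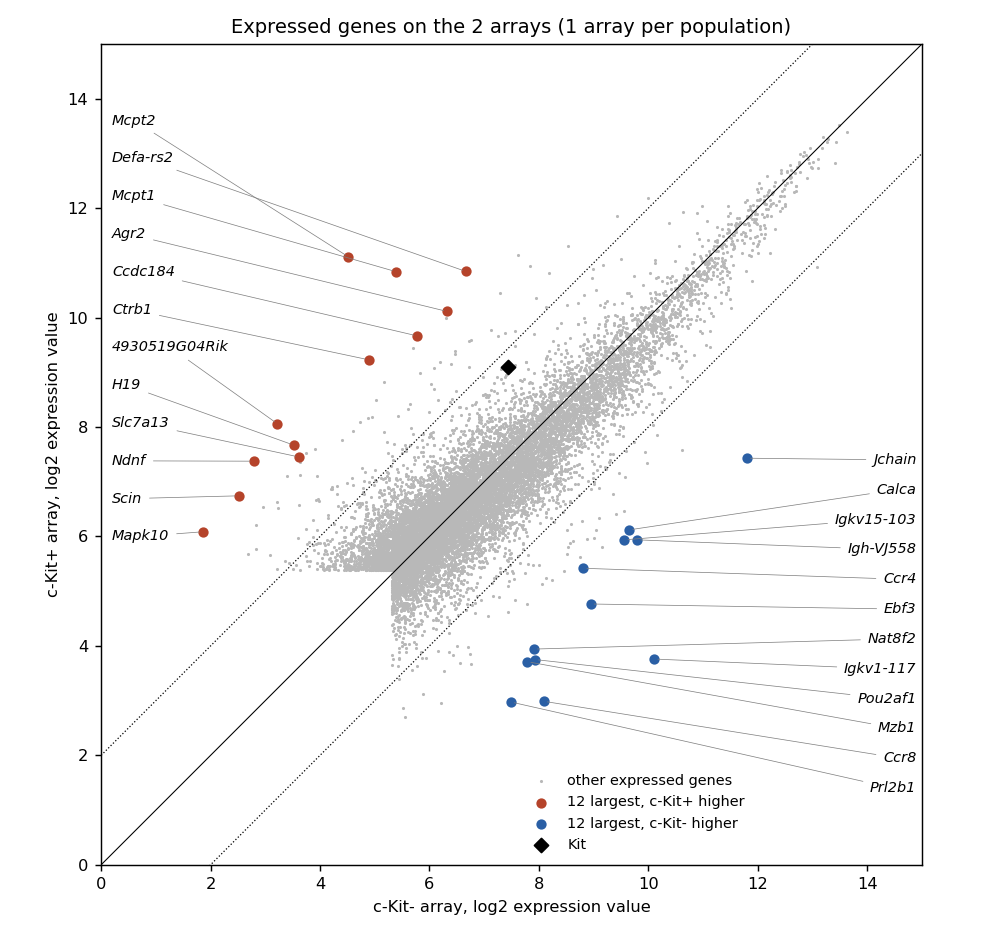
Log2 expression value of each expressed gene on the c-Kit- array (x axis) and the c-Kit+ array (y axis). The solid line marks equal values, the dotted lines mark differences of 2 log2 units, red and blue points are the 12 largest differences on each side, and Kit (black diamond) lies 1.67 above the line of equal values.

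Among genes with a probe set of a single symbol, the largest excess on the c-Kit+ array belonged to mast cell proteases. Mcpt2 read 11.11 on the c-Kit+ array and 4.52 on the c-Kit- array, 96.3-fold higher, and Mcpt1 read 10.84 and 5.39, 43.8-fold higher. Both encode chymases of mucosal mast cells and belong to a family of similar genes, so cross-hybridization between family members was not ruled out. The other genes among the 12 largest on this side were of mixed kinds. Ctrb1, a pancreatic digestive enzyme, was 20.3-fold higher, and Defa-rs2, an antimicrobial peptide gene of Paneth cells, was 18.1-fold higher. Agr2, a protein-folding factor of mucus-secreting cells, was 13.8-fold higher (2.14 log2 units with its least different probe set), and the actin-severing protein gene Scin was 18.7-fold higher, a log2 difference that shrank by more than 1.5 times with a pseudocount of 16. The imprinted noncoding RNA H19 was 17.7-fold higher. The remaining members were 4930519G04Rik (28.6-fold), Ndnf (24.1-fold), Mapk10 (18.7-fold), Ccdc184 (14.8-fold) and Slc7a13 (14.3-fold). For Mapk10 the difference rests on a single probe set of a cross-hybridizing type, and without such probe sets it was -0.089. Probe sets of 4930519G04Rik, Ndnf and Slc7a13 below the expression filter differed by as little as 0.24, 0 and 0.62.

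On the c-Kit- side of the same ranking, immunoglobulin and plasma cell transcripts led. An immunoglobulin kappa variable gene, of the V5 family by the file's title, read 3.76 on the c-Kit+ array and 10.11 on the c-Kit- array, 81.5-fold higher on the latter. Jchain, which joins secreted IgA and IgM, was 20.7-fold higher on the c-Kit- array. Pou2af1, a transcriptional coactivator of B lineage cells, was 18.1-fold higher, and Mzb1, a chaperone for antibody secretion, 16.9-fold higher. The heavy chain gene Igh-VJ558 and a kappa variable gene of the V32 family were 14.5-fold and 12.3-fold higher. Immunoglobulin segments share sequence, so single segments were not separated, and another probe set of the V5 gene, below the expression filter, differed by -0.044. The chemokine receptor genes Ccr8 and Ccr4 were 34.3-fold and 10.5-fold higher, and Calca, which encodes calcitonin gene-related peptide, was 11.6-fold higher. The last members were Prl2b1 (22.8-fold), Ebf3 (18.1-fold) and Nat8f2 (15.6-fold). Probe sets of Ebf3, Nat8f2 and Igh-VJ558 below the expression filter were higher on the c-Kit+ array, by 0.50, 0.15 and 0.38, and another of Prl2b1 differed by -0.42.

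Genes of type 3 innate lymphoid cells (ILC3) and LTi cells stood higher on the c-Kit+ array as a list, but most of its members were nearly level. Of 22 expressed members, 6 were higher by 1 log2 unit or more, none was lower by as much, and 16 lay within 1. The list's median of 0.21 was above the central 95% of random lists of matched expression (-0.44 to 0.06), and 4 of 10000 random lists had a median as high. Ccr6, the receptor for CCL20, was 12.6-fold higher (8.82 against 5.17). By their brightest probe sets Tnfsf11, which encodes RANK ligand, was 7.62-fold higher, the interleukin 1 receptor gene Il1r1 6.70-fold and the oxysterol receptor gene Gpr183 4.22-fold higher. Their least different probe sets gave 1.23, 0 and 0.56 log2 units. The lymphotoxin gene Lta was also past 1 (3.07-fold). Members that read alike included the interleukin 7 receptor gene Il7r (10.72 and 10.70) and Ahr (7.90 and 7.88), and Ncr1, which encodes NKp46, read 7.56 and 8.07. Interleukin 22 itself is measured by a single probe set that also names the paralog Iltifb, and it read 12.72 on the c-Kit+ array against 7.14, 47.9-fold higher. It was chosen after its values were seen, because the naming rule takes only probe sets of 1 symbol. Il17a read 6.60 and 6.05. Mast cell, Paneth cell and early-response transcripts were also higher on this array, as given below.

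Mast cell genes formed the list with the second highest median, 1.68 over 16 expressed members. Of these, 11 were higher on the c-Kit+ array by 1 log2 unit or more and none was lower by as much, and none of the 10000 random lists had a median as high (95% range -0.37 to 0.30). The median was 2.69 under the stricter expression filter. Beside Mcpt2 and Mcpt1, the IgE receptor chain gene Fcer1a was 10.0-fold higher and the transcription factor gene Gata2 6.94-fold higher, or 1.53 log2 units with its least different probe set. Kit, which is also on this list, was part of the gate. The basophil list, with a median of 2.42 over 6 expressed members, shares Fcer1a, Gata2, Cpa3 and Ms4a2 with the mast cell list. Il4, which it shares with the ILC2 list, was 4.82-fold higher on the c-Kit- array instead. Without shared members the basophil list holds 1 expressed gene, the protease gene Mcpt8 (4.31-fold higher), so that part of it rests on a single gene. The list of hematopoietic progenitor genes had a median of 0.43, just above its random range of -0.48 to 0.41. Its leading members were Gata2 and Cd93 (higher by 1.32 log2 units), and its median was inside the range under 4 of the 10 alternatives, one of them without members shared between cell type lists.

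Paneth cell genes, several of which encode antimicrobial products of the crypt base, had a median of 1.11 over 8 expressed members. Of these, 4 were higher on the c-Kit+ array by 1 log2 unit or more and none was lower by as much. Defa24 was 11.5-fold higher (11.15 against 7.63), Nupr1 3.98-fold (1.13 log2 units with its least different probe set), Pla2g2a 3.19-fold and Itln1 2.82-fold higher. The other expressed members Lyz1, Mmp7, Reg3g and Reg3b differed by 0.72, 0.38, -0.17 and -0.84. Defa3, below the expression filter, differed by 0.28. None of the 10000 random lists had a median as high (95% range -0.53 to 0.34). With no expression filter the median was 0.55. Defensin genes are near-identical, so the probe sets cannot tell single members apart. The general epithelial list moved both ways, with a median of -0.23 inside its random range (-0.45 to 0.22). The goblet cell genes Tff3 and Muc2 were 5.27-fold and 3.55-fold higher on the c-Kit+ array, whereas the stem cell gene Olfm4 and the keratin gene Krt8 were 9.56-fold and 2.89-fold higher on the c-Kit- array. With a pseudocount of 16 Olfm4 differed by -1.93 log2 units.

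Genes of type 2 innate lymphoid cells (ILC2) had the lowest median of all lists. It was -1.59 over 13 expressed members, below all 10000 random lists (95% range -0.53 to 0.18). On the c-Kit- array 8 members were higher by 1 log2 unit or more, and on the c-Kit+ array none was. Calca was 11.6-fold higher on the c-Kit- array, the interleukin 25 receptor gene Il17rb 7.97-fold, and the transcription factor genes Bcl11b and Gata3 5.23-fold and 4.93-fold higher. The least different probe set of Bcl11b gave -1.05 log2 units. The type 2 cytokine genes Il5 and Il13 were 3.20-fold and 2.79-fold higher. Several of these genes, among them Gata3, Bcl11b and Il4, are also used by T cells.

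T cell genes were higher on the c-Kit- array although both populations were sorted as lineage negative. The median was -1.37 over 18 expressed members, below all 10000 random lists (95% range -0.43 to 0.14). Of these members 11 were higher on the c-Kit- array by 1 log2 unit or more and none was higher on the c-Kit+ array by as much. The CD3 chain genes Cd3e and Cd3d were 8.20-fold and 7.15-fold higher (Cd3e at 10.62 against 7.59), and Cd5 and Cd28 were 7.37-fold and 5.96-fold higher. The T cell genes Cd8b1, Trat1 and Themis differed by 0, 0.23 and -0.44 log2 units. Natural killer cell and ILC1 genes had a median of -1.04 over 15 expressed members, again below all random lists (95% range -0.49 to 0.11). On the c-Kit- array 8 members were higher by 1 or more. The perforin gene Prf1 was 3.76-fold higher, Nkg7 3.64-fold, Klre1 3.21-fold and the interferon gamma gene Ifng 3.05-fold higher. The granzyme gene Gzmb read alike, at 11.13 on the c-Kit+ array and 11.05 on the c-Kit- array. The receptor genes Klrd1, Ncr1, Klrk1 and Klrb1c differed by -1.28, -0.51, -0.43 and -0.10 log2 units. Whether the members past 1 came from natural killer cells, ILC1 or T cells was not tested.

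The B and plasma cell list had a median of -0.69 over 14 expressed members (95% range of random lists -0.40 to 0.27), with 7 members higher on the c-Kit- array by 1 or more and 1 higher on the c-Kit+ array. Jchain, Pou2af1 and Mzb1 led, the heavy chain gene Ighm was 4.12-fold higher, and Tnfrsf17, the plasma cell receptor BCMA, was 2.74-fold higher. The kappa light chain gene Igk was 4.24-fold higher, but differed by -0.25 log2 units with its least different probe set. The B cell genes Ms4a1, Pax5 and Cd79b differed by 0.037, -0.099 and -0.33. The exception on the c-Kit+ side was Sdc1, which encodes syndecan 1 of plasma cells and epithelium, at 2.93-fold. The median was inside the random range when no expression filter was used and when each gene took its least different probe set.

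**Figure D2:**
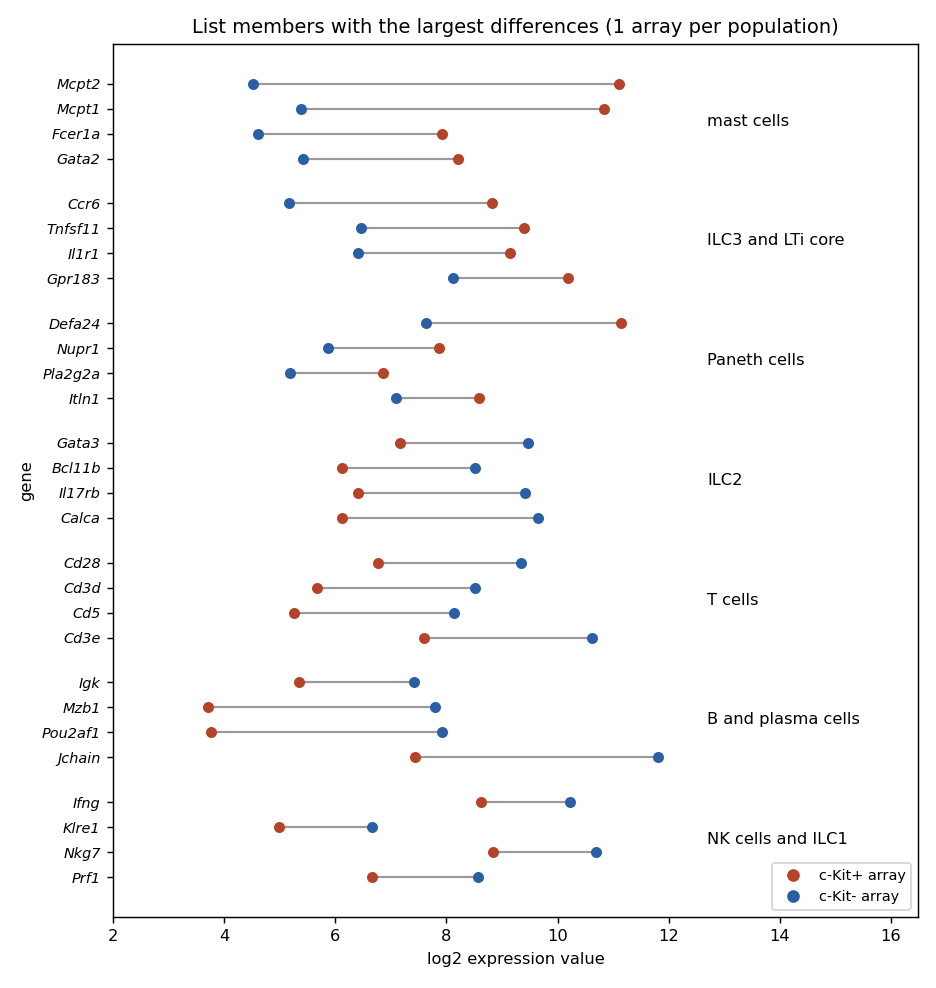
Log2 expression values (x axis) on the c-Kit+ array (red) and the c-Kit- array (blue) of the 4 expressed members with the largest differences in each of 7 cell type lists. In the first 3 lists the c-Kit+ value is higher for every gene shown, and in the last 4 lists the c-Kit- value is.

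Of 19 expressed chemokine receptor genes, 5 were higher on each array by 1 log2 unit or more and 9 lay within 1. The median of -0.34 was inside the random range (-0.40 to 0.16), and below its range under the stricter expression filter (-0.70) and with the least different probe sets. Ackr3 (13.0-fold) and Ccr6 led on the c-Kit+ array, together with Cxcr5 (9.70-fold), the receptor for the follicle chemokine CXCL13. Ccr8 and Ccr4 led on the c-Kit- array, together with the gut-homing receptor gene Ccr9 (3.84-fold). Among 13 TNF superfamily ligand genes, 4 were higher on the c-Kit+ array by 1 or more and 3 on the c-Kit- array. The median of 0.093 was inside the random range (-0.45 to 0.37), and above it under the stricter expression filter. Tnfsf11 and Lta were on the c-Kit+ side, and the CD40 ligand gene Cd40lg (7.07-fold) and the Fas ligand gene Fasl (3.76-fold) on the c-Kit- side. Cytokine genes had a median of -0.49 (random range -0.43 to 0.18), with 7 of 17 expressed members higher on the c-Kit- array by 1 or more and 1 on the c-Kit+ array. Il22 was fixed on this list but is not counted, because its probe set names several symbols. That probe set was higher on the c-Kit+ array by 5.58 log2 units. Flt3l was 7.62-fold, Il4 4.82-fold and Il5 3.20-fold higher on the c-Kit- array, and the leukemia inhibitory factor gene Lif was 3.63-fold higher on the c-Kit+ array (0.79 log2 units with its least different probe set). The cytokine median was inside the random range without members shared between cell type lists and with no expression filter. Among 32 expressed cytokine receptor genes, whose median was below the random range under 4 of the 10 alternatives, 1 was higher on the c-Kit+ array (Il1r1) and 4 on the c-Kit- array, led by Il17rb and Csf2ra (3.71-fold).

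Among 25 expressed lymphoid transcription factor genes, with a median of -0.18 inside the random range, 20 lay within 1 log2 unit. The members Bcl11b, Gata3, Tbx21 (2.79-fold) and Lef1 (2.07-fold) were higher on the c-Kit- array by 1 or more. Genes of major histocompatibility complex class II presentation had a median of -0.51 (random range -0.45 to 0.18), and 10 of 12 lay within 1. The members past 1 were Ciita (2.19-fold) and H2-DMb2 (2.15-fold), of which Ciita differed by -0.14 with its least different probe set. The list was inside the random range under the stricter expression filter and with the least different probe sets. Integrin genes had a median of -0.44, at the edge of a random range of -0.44 to 0.15, and Itga1 (3.47-fold higher on the c-Kit- array) was their only member past 1, although its least different probe set gave -0.87. The integrin median was inside the range under 5 of the 10 alternatives. Early-response and heat shock genes, which respond to cell handling, had a median of 0.14 (random range -0.40 to 0.045) over 20 expressed members. Of these, 4 were higher on the c-Kit+ array by 1 or more, namely Atf3 (3.26-fold), Ier3 (2.60-fold), Jun (2.57-fold) and Hspa1b (2.03-fold), and none was lower by as much. The median was inside the range of random lists drawn without matching, and Hspa1b differed by -0.024 with its least different probe set.

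The medians of the other fixed lists were inside their random ranges in the main analysis, and some left them under an alternative. Macrophage and dendritic cell genes had a median of 0.13 with 11 of 20 measured members expressed, and Zbtb46 (3.97-fold) and Cx3cr1 (2.89-fold) were higher on the c-Kit+ array, although another probe set of Cx3cr1 differed by -0.44. The medians were 0.32 for eosinophils, -0.05 for neutrophils, -0.09 for fibroblasts, 0.02 for smooth muscle and -0.22 for interstitial cells of Cajal, the c-Kit-bearing pacemaker cells of the gut wall. They were -0.29 for endothelium, -0.22 for enteric glia and neurons and 0.48 for erythroid cells. The last rests on 2 weak members, Epb42 and Slc4a1, and hemoglobin probe sets of several symbols, which the list leaves out, went the other way (alpha chain -1.49 to -1.19, beta chain -3.20). Among functional lists the medians were 0.13 for chemokines, -0.30 for cytokine receptors, -0.39 for Toll-like and NOD-like receptor signalling and -0.37 for the Notch pathway. They were -0.29 for targets of the aryl hydrocarbon receptor, 0.24 for the retinoic acid pathway, -0.07 for proliferation, -0.15 for the interferon response and 0.02 for housekeeping genes. Of these lists, eosinophils and chemokines were above their range with no expression filter. The Notch list was below with no filter and with the mean of probe sets, Toll-like and NOD-like receptor signalling without cross-hybridizing probe set types, and enteric glia and neurons with the least different probe sets. Over all 35 lists, 6 medians lay above their random range, 7 below and 22 inside, where 1.75 outside would be expected by chance. Members of a list vary together, which random lists do not carry, so these ranges are narrower than a list's own sampling range.

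**Figure D3:**
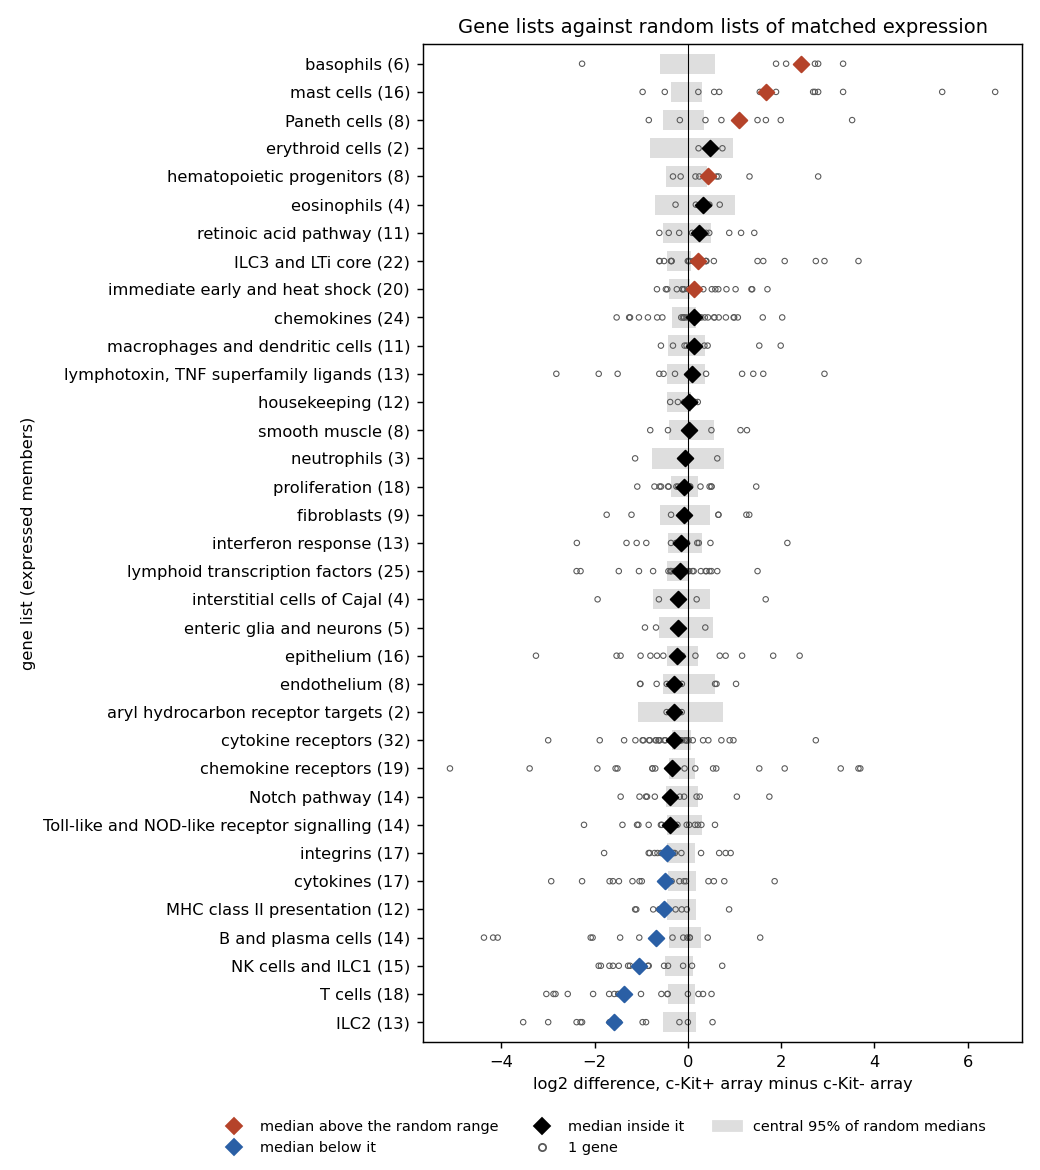
Log2 difference between the arrays (x axis, c-Kit+ minus c-Kit-) for the expressed members of each list fixed in advance (open circles) with the list's median (diamond) and the central 95% of 10000 random lists (grey bar). Basophil, mast cell and Paneth cell medians lie to the right of their bars, at 2.42, 1.68 and 1.11, and ILC2, T cell, and NK cell and ILC1 medians to the left, at -1.59, -1.37 and -1.04.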

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

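No explanation was tested in this part. The 18 probe sets listed in this paragraph were left out of the gene comparisons, because they name several genes or none, and each differed by 3 log2 units or more between the arrays while passing the expression filter. No other kind of flag could be applied with 1 array per group. Higher on the c-Kit+ array were the probe set of Il22 and Iltifb (by 5.58), that of Defa5 and similar defensins (4.91), that of Ceacam1 and Ceacam2 (3.03), and a pair of probe sets without a symbol (3.26 and 3.12). Lower on the c-Kit+ array were probe sets of immunoglobulin lambda, with differences of -4.87 and -4.67, of kappa segments, at -3.79 and -3.04, and of the heavy chain, at -3.37. The hemoglobin beta probe set (Hbb-b1 and Hbb-b2) differed by -3.20, that of Brd1 and LOC100045983 by -3.70, and that of LOC100047222 and LOC676193 by -3.41. Probe sets without a symbol on this side differed by -6.41, -5.25, -3.61, -3.26 and -3.22, and the file titles that of -3.61 a single chain antibody. The authors' deposited table gives 47.9 as the fold of the Il22 probe set and 96.3 as that of Mcpt2.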

How the results depend on the processing

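All alternatives in this part were planned. The lists for ILC3 and LTi cells, mast cells, basophils, Paneth cells, ILC2, T cells, and NK cells and ILC1 stayed on the same side of their random range under all 10 alternatives, with medians of 0.11 to 0.34, 1.41 to 2.69, 2.04 to 2.72, 0.55 to 1.58, -1.66 to -1.39, -1.49 to -0.99 and -1.24 to -0.86. Without members shared between cell type lists the basophil list holds 1 expressed gene, Mcpt8. Of the other lists outside their range, B and plasma cells, class II presentation and cytokines were inside it under 2 alternatives, integrins under 5, hematopoietic progenitors under 4 and early-response genes under 1, and 8 of the 22 lists inside their range left it under at least 1 alternative. A pseudocount of 16, which shrinks low values by construction, gave 458 and 609 genes past 1 log2 unit (c-Kit+ side first), 63 and 48 past 2, and 13 and 12 past 3, and 62 and 48 of those past 2 were among the genes of the main setting. Taking the probe set with the smallest difference, which lowers counts by construction, gave 441 and 435, 78 and 51, and 21 and 13. The mean of all probe sets gave 548 past 1 and 55 past 2 on the c-Kit- side and 22 past 3 on the c-Kit+ side, and the filter at the 75th percentile gave 452 past 1 on the c-Kit+ side. Medians that moved by more than the probe set scatter of 0.43 were those of mast cells (2.69), Paneth cells (1.58), neutrophils (0.63), smooth muscle (0.56), hematopoietic progenitors (0.97) and TNF superfamily ligands (0.64) under the 75th percentile filter, of TNF superfamily ligands with the mean of probe sets (-0.40), of Paneth cells (0.55) and B and plasma cells (-0.21) with no filter, and of B and plasma cells (-0.21) and enteric glia and neurons (-0.67) with the smallest difference. The naming rule was here also applied to the lists added after values had been seen. Of 113 genes past 1 log2 unit that it then takes 9 changed sign, in each case where another probe set was taken, as did 9 of 40 under 1 under some alternative. Mapk10 (-0.089) and Ebf3 (0.57) did so without _x_at and _s_at, and Mapk10 (-0.089), Ebf3 (0.50), Nat8f2 (0.15), Igh-VJ558 (0.38), Cx3cr1 (-0.44), Acta2 (-0.084), Tlr12 (0.10), Nrarp (0.056) and Hspa1b (-0.024) did so with the smallest difference. Except where the construction is named, the cause was not tested. No paired analysis was possible because each population has 1 array. No signal over background was given, so how much background the weak values carry was not measured.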

Other observations

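The tests on goblet and pancreatic genes below were written before the values of those genes were seen, and the other tests in this part were chosen after the result was seen. Hemoglobin transcripts were higher on the c-Kit- array, against the direction of the erythroid list, with differences of -1.49 to -1.19 log2 units in the 3 alpha chain probe sets that name both Hba-a1 and Hba-a2 and of -3.20 in the beta chain probe set. The 3 expressed T cell receptor alpha probe sets that name Tcra and A130082M07Rik were higher on the c-Kit- array, with differences of -2.70 to -2.41, and read up to 11.28, whereas the probe set that names Tcra alone was higher on the c-Kit+ array by 0.33. The interferon response list stayed inside its random range, with its leading members on opposite sides. Ifit1 was 5.21-fold and Irf7 2.49-fold higher on the c-Kit- array, and Oasl2 was 4.39-fold higher on the c-Kit+ array. In the Notch list the ligand gene Dll1 was 3.36-fold higher on the c-Kit+ array and Jag1 2.72-fold higher on the c-Kit- array, although another probe set of Jag1 differed by -0.42. Nod1, an intracellular sensor of bacterial cell wall fragments, was 4.68-fold higher on the c-Kit- array, and the retinoic acid degrading enzyme gene Cyp26a1 was 2.68-fold higher on the c-Kit+ array (0.92 log2 units with a pseudocount of 16).

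Mast cell transcripts were among the largest differences on the c-Kit+ array, in a population gated on c-Kit, which mast cells also carry. Scatter of single probe sets is argued against, since 0 of 10000 matched random lists had a median as high as the list fixed in advance. Mast cells in the c-Kit+ sort remain a candidate explanation. Mcpt2 and Mcpt1 read 11.11 and 10.84 there, and the 10 expressed members on no other cell type list, Kit left out, had a median of 1.60, with 6 higher by 1 or more and none lower by as much. Mcpt2 and Mcpt1 are among these 10, so this median is the pattern itself and does not test the explanation. Expression of these genes by the innate lymphoid cells themselves was not tested and stays open, as bulk arrays do not assign a transcript to a cell.

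T cell and plasma cell transcripts were higher on the c-Kit- array, although both gates excluded lineage-positive cells. A lower share of innate lymphoid cells on that array would raise all other cell types alike. The median of mast cell genes on no other cell type list (1.60) lay 2.97 log2 units above that of the T cell list. This cannot decide the question, because mast cells carry c-Kit and the gate itself would place them on the c-Kit+ array. T cells in the c-Kit- sort remain a candidate for the T cell part, but the list median (-1.37) is the pattern itself and does not test this. For the immunoglobulin part, plasma cells cannot be told apart from other sources, because the 6 plasma cell genes looked at (median -2.77) were chosen after the pattern was seen and so test nothing. The composition of the lineage cocktail is not stated in the labels, T cells also use several ILC2 genes, and how far each cell type contributes was not tested, nor was a biological explanation.

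Defensin and pancreatic enzyme transcripts were higher on the c-Kit+ array, as were the goblet cell genes Tff3, Muc2 and Agr2, which were seen first and do not stand for goblet cell genes as a group. An excess of epithelial cells of every kind in that sort over the c-Kit- sort is argued against. Of the expressed epithelial list, 7.14% (1 of 14, Muc2 and Tff3 left out) was higher by 1 or more and 4 were lower by as much. A difference between arrays cannot tell whether both sorts held epithelial cells. Epcam read 8.64 on the c-Kit+ array and 7.83 on the c-Kit- array. For goblet cells or their RNA, a median below the 90th percentile of random lists (0.16) was set beforehand as the outcome against them. The 12 goblet genes not seen before had a median of -0.016, below that limit and inside their random range (-0.43 to 0.29). By that limit the outcome is against goblet cells for these genes as a group. It cannot decide the question, because some of the genes were weak on both arrays. Spdef read 5.33 on the c-Kit+ array and 5.42 on the c-Kit- array, and Tpsg1 5.45 and 5.55, close to the medians that set the expression filter. The upper quartile of the 12 genes was 0.61, and 2 were higher by 1 or more. The abundant members went separate ways, with Spink4 higher by 2.19, Guca2a by 2.34 and Zg16 differing by -0.29. A goblet cell source of single genes was not tested and stays open. Pancreatic RNA carried into the c-Kit+ sort may contribute. Of 14 measured acinar genes not seen before, the 7 expressed had a median of 0.65 against a random range of -0.49 to 0.60, a narrow margin. The median of this list was not computed under the processing alternatives. As a single gene its member Sycn differed by 1.13 in the main setting and by as little as 0.25 under an alternative. The 10 expressed pancreatic enzyme genes seen beforehand, among them Pnlip and Prss2, had a median of 1.75, which tests nothing because they were chosen after their values were seen.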
